A study of Homo sapiens with 28 samples.

How the data were processed

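The series measured the abundance of guide RNAs of the EPIKOL library by sequencing in 5 prostate cell lines at a baseline and at an endpoint. Per the labels' protocols, cells carrying lentiCas9-blast were infected with the library in lentiGuide-puro at a multiplicity of infection of 0.3 with 500 cells per sgRNA. Puromycin began after 48 hours and ran for 3 days, and the endpoint came 15 doublings after the baseline. Guides were amplified from 4 µg of genomic DNA in PCRs of 25 and 15 cycles. LNCaP grew in medium with serum, LNCaP-abl in medium with charcoal-stripped serum, MR49F and ENZA-R with 10 µM enzalutamide, and RWPE-1 in keratinocyte serum-free medium, per the labels.

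The authors deposited 4 tables of normalised sgRNA signal values, with a column per library, per the file headers. The submitters' processing notes name MAGeCK, and its version and options are not given in the sources used here. Each column held whole multiples of a single step, so whole reads recovered by dividing by that step (100% of values within 0.0100 reads) gave the depth of each library, from 3209959 to 12108984 reads. PCR reads without molecular identifiers are not independent molecules, so depth covers counting error alone. The authors also deposited a MAGeCK gene summary per line. Per the file headers it holds a log2 fold change per gene, a score for depletion and for enrichment, a rank, and a p-value with its FDR for each. These summaries were read only for values named as the authors' deposited table.

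Tables differed by line: LNCaP, MR49F and ENZA-R each had a table of their own, and LNCaP-abl and RWPE-1 shared 1, so each change was computed within a table. Groups came from the labels. The ENZA-R columns carry replicate numbers 2 and 3, which are used here, while the labels number these libraries from 1. Of 779 gene symbols 755 were current symbols in the reference table of gene names and 24 older ones, printed as in the files. Of these genes 775 had 10 sgRNAs and 4 had fewer, at least 4.

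For each sgRNA the log2 of the deposited value plus a pseudocount of 1 was taken relative to its mean over the line's baseline libraries, and the gene value in a library was the median over its sgRNAs. Genes with at least 3 sgRNAs were tested, and the non-targeting sgRNAs were kept out. Endpoint minus baseline was fitted per line with limma (lmFit and moderated eBayes, two-sided), and differences between lines as the interaction of line and time point over the libraries of both lines. A call needed a Benjamini-Hochberg adjusted p under 0.0500 over all genes and a log2 change of at least 0.500 in size. Gene lists written before the data were examined were tested with camera at an inter-gene correlation of 0.0100, adjusted over 27 lists, and again with an estimated correlation. They cover the SWI/SNF forms and their join, PRC1, PRC2, NuRD, COMPASS/MLL, NuA4/SRCAP/INO80, SAGA/ATAC, HBO1/MOZ and MSL/NSL, ISWI/CHD, SIN3 and NCOR, CoREST/LSD1, BET and p300/CBP, histone chaperones, chromatin kinases, writers and erasers of histone and DNA methylation, HDAC and sirtuin enzymes, androgen signalling genes, growth-restraining genes, core essential controls and tissue-restricted negative controls.

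The genes named were set by a rule before the data were examined. In each line it takes the 10 most depleted called genes outside the core essential list, the 3 most depleted within it, the 5 most enriched and every called SWI/SNF member. In each comparison of lines it takes the 6 lowest and 4 highest called differences outside the core list and every called SWI/SNF member. In a line, genes were ranked among those whose endpoint libraries all lay on the same side of all baseline libraries. In a comparison, the endpoint values of the first line all had to lie on the same side of those of the second. These endpoint values were relative to each line's own baseline. For each other list up to 2 called members are named in the line where their change is largest. Genes named outside this rule were chosen after their values were seen. Results on some genes the rule takes are left out because those genes are withheld for evaluation, and Y-linked genes are not named.

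The alternatives were a pseudocount of 5, leaving out sgRNAs under 30 at baseline, the mean over sgRNAs, centring each library on the median non-targeting sgRNA, no minimum size of change, the replicate number as a block, each library left out in turn, and edgeR's quasi-likelihood test on the recovered reads. For edgeR the reads of a gene were summed over its sgRNAs and scaled with edgeR's own normalisation factors. Its log2 values are therefore another measure of the gene than the median sgRNA. With a library left out of ENZA-R the lone library is assumed to vary like the other group. Keeping ENZA-R sgRNAs of at least 100 in every baseline library was added after seeing the data. The fits were tested on simulated data with 200 changed genes and a single dispersion per group, set from the median spread of its sgRNAs. In LNCaP 100% of genes changed by -1 and 77.5% of those changed by -0.6 were called. All sgRNAs of a changed gene were given the same change, so these rates are likely too high for genes whose sgRNAs differ. Software was R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.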

Results

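The series is a pooled CRISPR-Cas9 knockout screen with EPIKOL, a guide library against regulators of chromatin, in 5 prostate lines. LNCaP is an androgen-sensitive line from a metastasis of prostate cancer. LNCaP-abl is a derivative kept in medium stripped of steroid hormones. MR49F and ENZA-R are lines resistant to enzalutamide, an antiandrogen, and were grown with 10 µM of it. RWPE-1 is an immortalised line of non-cancerous prostate epithelium. Cas9-expressing cells took up the guides at a multiplicity of infection of 0.3 and were sequenced after 3 days of puromycin (baseline) and again after 15 doublings (endpoint). A guide whose target the cells need becomes rarer between these points. There were 3 baseline and 3 endpoint libraries for each of LNCaP, LNCaP-abl, MR49F and RWPE-1, and 2 of each for ENZA-R, 28 libraries in all. Each table held 7855 guides (sgRNAs), of which 7775 targeted 779 genes and 80 were non-targeting. The recovered totals ran from 3209959 reads in LNCaP-abl baseline replicate 2 to 12108984 reads in LNCaP baseline replicate 3, with a median of 374 to 1387 reads per sgRNA. The labels call the replicates biological but do not describe separate cultures, so the p-values measure the spread between these libraries.

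Gene values are log2 changes from baseline to endpoint of a gene's median sgRNA, ± SE of the limma fit, with adjusted p from limma and the Benjamini-Hochberg method. A gene was called depleted or enriched at an adjusted p under 0.05 and a change of at least 0.5. Values from edgeR rest on reads summed over a gene's sgRNAs and on edgeR's own scaling, so they are not a second test of the median sgRNA. All other values are relative to the authors' scaling, under which the median gene changed by 0.064 in LNCaP, 0.046 in LNCaP-abl, 0.050 in MR49F, 0.16 in ENZA-R and 0.084 in RWPE-1. Non-targeting sgRNAs lay above that level, with a mean over endpoint libraries of 0.53 ± 0.099 (SD, n = 3), 0.48 ± 0.089 (SD, n = 3), 0.48 ± 0.048 (SD, n = 3), 0.67 ± 0.074 (SD, n = 2) and 0.63 ± 0.057 (SD, n = 3) in the same order. Centring on those sgRNAs moved the median gene to -0.44, -0.43, -0.42, -0.50 and -0.54, so enriched genes are also placed relative to them.

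The LNCaP screen asked which chromatin regulators the parental line needs. Guides against FOXA1, a pioneer transcription factor, fell by 1.81 ± 0.15 (adjusted p = 9.27e-06), and all 10 of them were lower at the endpoint. KMT2D, a methyltransferase of histone H3 lysine 4 at enhancers, fell by 1.33 ± 0.20. Also among the most depleted genes were PPP4C, a phosphatase catalytic subunit, at -1.65 ± 0.23, SS18L2 at -1.61 ± 0.17, the ribosomal protein gene RPL18 at -1.54 ± 0.17, topoisomerase TOP2A at -1.52 ± 0.13, the rRNA methyltransferase FBL at -1.48 ± 0.21, the spliceosome gene SNRPF at -1.48 ± 0.15 and the RNA-binding protein gene SFPQ at -1.47 ± 0.19. In total 160 of 779 genes were depleted and 33 enriched.

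Core essential controls behaved as a group: 23 of 25 fell in LNCaP, with a median of -1.17, led by PCNA at -1.95 ± 0.17 and RPL11 at -1.79 ± 0.13. The camera adjusted p was 3.76e-14 with the preset correlation, and adjusted p = 0.0652 with an estimated correlation. Among the most enriched genes were TP53BP1, a DNA break response protein, at 0.82 ± 0.13, ARID4A at 0.75 ± 0.14, UBE2D1 at 0.74 ± 0.12 and WHSC1 at 0.68 ± 0.13. All 3 genes of the growth-restraining list rose, with a median of 0.82 (camera adjusted p = 0.0158; adjusted p = 0.359 with an estimated correlation). Relative to the non-targeting sgRNAs TP53BP1 stood at 0.31 (adjusted p = 0.0839), ARID4A at 0.25, UBE2D1 at 0.23 and WHSC1 at 0.18, without passing. With that centring 345 genes were depleted and 1 enriched.

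In LNCaP 2 other lists passed, both downward. Of 19 COMPASS/MLL genes, which place methyl groups on histone H3 lysine 4, 8 fell (median -0.44, camera adjusted p = 0.0158; adjusted p = 0.359 with an estimated correlation). Of 31 members of the NuA4, SRCAP and INO80 complexes, 9 fell (median -0.26, camera adjusted p = 0.0120; adjusted p = 0.359 with an estimated correlation). EED, a core subunit of PRC2, fell by 0.89 ± 0.13. AEBP2, the other depleted PRC2 gene, changed by -0.63 ± 0.17 and lost its call without LNCaP baseline replicate 2 or LNCaP endpoint replicate 1 (range -0.80 to -0.43 over the fits that left out 1 library). KDM1A, the LSD1 demethylase, changed by -0.84 ± 0.24 and lost its call without LNCaP baseline replicate 2 or LNCaP endpoint replicate 1 (range -1.18 to -0.57). UHRF1, of the DNA methylation list, changed by -0.53 ± 0.19 and lost its call without LNCaP baseline replicate 2 or 3 or LNCaP endpoint replicate 3 (range -0.72 to -0.28). DR1 of the SAGA/ATAC list fell by 1.10 ± 0.14. edgeR on the recovered reads called 124 genes depleted and 13 enriched. Of the genes named for LNCaP it did not call KDM1A (-0.19, adjusted p = 0.113), AEBP2 (-0.40, adjusted p = 0.00595) or ARID4A (0.496, adjusted p = 5.69e-05).

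LNCaP-abl grows without added androgen and asks which needs persist there. FOXA1 again was among the most depleted genes, at -1.79 ± 0.22 (adjusted p = 5.24e-05). SFPQ led at -2.02 ± 0.11 (adjusted p = 1.49e-07), followed by RPL18 at -1.91 ± 0.15, TOP2A at -1.82 ± 0.19, FBL at -1.71 ± 0.18 and the deubiquitinase USP7 at -1.71 ± 0.11. HUWE1, a ubiquitin ligase, stood at -1.58 ± 0.095, RPS15A at -1.58 ± 0.21, TRMT112, a cofactor of several methyltransferases, at -1.57 ± 0.14, and the oncogene MYC at -1.56 ± 0.12. In total 140 genes were depleted and 8 enriched. Of the core essential controls 23 of 25 fell (median -1.08, camera adjusted p = 2.89e-15; adjusted p = 0.105 with an estimated correlation), with RPL11 at -1.89 ± 0.11, the splicing gene PRPF19 at -1.70 ± 0.11 and the nuclear import gene KPNB1 at -1.56 ± 0.15.

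Among the most enriched genes in LNCaP-abl were RB1, the retinoblastoma tumour suppressor, at 0.75 ± 0.14, INO80D at 0.69 ± 0.10, ATN1 at 0.67 ± 0.12 and the H3K27 demethylase KDM6A at 0.66 ± 0.13. Relative to the non-targeting sgRNAs limma called 0 genes enriched and 327 depleted, with RB1 at 0.28 (adjusted p = 0.102). The count of enriched genes was 8 with all libraries and 18 without LNCaP-abl endpoint replicate 2, and edgeR on the recovered reads called 4. Of 14 chromatin kinases 5 fell (median -0.34, camera adjusted p = 0.0381; adjusted p = 0.618 with an estimated correlation). The 15 DNA methylation genes lay higher than other genes (median 0.27, camera adjusted p = 0.0381; adjusted p = 0.618 with an estimated correlation), but below the non-targeting level. SIRT6 changed by -0.50 ± 0.10, a call lost without LNCaP-abl baseline replicate 3 or LNCaP-abl endpoint replicate 1 or 2 (range -0.60 to -0.45). edgeR did not call SIRT6 (-0.21, adjusted p = 0.0424).

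In MR49F the deepest changes outside the control list were in TOP2A at -1.46 ± 0.12 (adjusted p = 5.05e-07), PPP4C at -1.31 ± 0.11, UBL5 at -1.23 ± 0.11, the arginine methyltransferase PRMT5 at -1.21 ± 0.13, FBL at -1.20 ± 0.12 and SUPT16H, a subunit of the histone chaperone FACT, at -1.18 ± 0.12. GTF3C4 stood at -1.17 ± 0.14, RBBP5, a shared COMPASS subunit, at -1.13 ± 0.13, DDX21 at -1.13 ± 0.12 and TRMT112 at -1.11 ± 0.12. FOXA1, named here after its value was seen, changed by -0.46 ± 0.20 without passing (adjusted p = 0.0747). The authors' deposited table for MR49F gave FOXA1 a log2 fold change of -0.56 and rank 225 for depletion, with a depletion FDR of 1.9e-05. In MR49F the deposited depletion FDR was under 0.05 for 534 of 779 genes. The missing limma call therefore does not show that MR49F can do without FOXA1. In total 145 genes were depleted and 18 enriched. Among core essential controls 20 of 25 fell (median -0.78, camera adjusted p = 1.00e-10; adjusted p = 0.365 with an estimated correlation), with PRPF19 at -1.45 ± 0.14, RPL11 at -1.31 ± 0.15 and CDC16 at -1.25 ± 0.13.

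Enriched genes in MR49F were led by ARID4A at 0.72 ± 0.14, SUV39H2, a histone H3 lysine 9 methyltransferase, at 0.69 ± 0.13, SFRP1 at 0.66 ± 0.13 and RB1 at 0.65 ± 0.12. Relative to the non-targeting sgRNAs limma called 0 genes enriched and 326 depleted, and edgeR on the recovered reads called 5 enriched and 99 depleted. Of the NuA4, SRCAP and INO80 members 11 of 31 fell (median -0.34, camera adjusted p = 0.000377; adjusted p = 0.365 with an estimated correlation). Of COMPASS/MLL genes 8 of 19 fell and 1 rose (median -0.31, camera adjusted p = 0.0357; adjusted p = 0.365 with an estimated correlation). DOT1L, the H3K79 methyltransferase, fell by 0.96 ± 0.13, PCGF1 of PRC1 stood at -0.81 ± 0.11 and ZMYM2 of the CoREST list at -0.68 ± 0.11. Of the genes named for MR49F edgeR did not call PRMT5 (-0.15, adjusted p = 0.219), SUPT16H (-0.32, adjusted p = 0.00307), RBBP5 (-0.46, adjusted p = 0.00201), DDX21 (-0.48, adjusted p = 0.000634), ZMYM2 (-0.35, adjusted p = 0.00836) or SUV39H2 (0.45, adjusted p = 0.00317).

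ENZA-R gave few calls. Guides against RPL18 fell by 4.38 ± 0.39 (adjusted p = 0.00900). USP7 stood at -4.03 ± 0.51, HMGB1, an abundant chromatin protein, at -3.97 ± 0.58 and KAT8, the H4K16 acetyltransferase, at -3.08 ± 0.41. The controls PCNA at -4.76 ± 0.54 and RPL36 at -4.22 ± 0.35 fell as well. SETDB1, which methylates histone H3 lysine 9, rose by 3.05 ± 0.41 (adjusted p = 0.0309), with all 10 sgRNAs higher, and stayed enriched relative to the non-targeting sgRNAs at 2.38 (adjusted p = 0.0278). These 7 genes, 6 depleted and 1 enriched, were the limma calls, of which edgeR did not call KAT8 (-0.039, adjusted p = 0.954). Core essential controls lay at a median of -2.01 (camera adjusted p = 9.74e-13; adjusted p = 0.360 with an estimated correlation), with 2 of 25 called over all genes and 17 when adjusted over the list alone.

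The ENZA-R libraries stood apart in noise. Log2 sgRNA values of the 2 baseline libraries correlated at 0.331 across sgRNAs, and those of the 2 endpoint libraries at 0.454, against 0.695 to 0.904 within the groups of the other lines. The change of the non-targeting sgRNAs had an SD of 1.42, against 0.276 to 0.417 elsewhere. Data were also simulated with the median spread of sgRNAs within each group. There 100% of genes changed by -2, 55% of those changed by -1 and 25% of those changed by 1 were called. Genes noisier than that are not covered: in the real libraries SMARCC2 at -3.65 ± 0.89 and ARID1B at -2.21 ± 1.14 were not called. Most core essential controls were not called either, so these rates are likely too high for this line. Leaving out a library moved the limma counts: 0 depleted and 0 enriched without baseline replicate 2, the same without baseline replicate 3, 90 and 47 without endpoint replicate 2, and 128 and 94 without endpoint replicate 3. Each such fit takes the spread of the lone library from the other group. The median SD of sgRNAs was 0.86 between endpoint libraries and 0.58 between baseline libraries. The counts without an endpoint library are therefore likely too high. With all libraries 148 genes had an unadjusted p under 0.05. The mean over sgRNAs in place of the median gave 52 depleted and 3 enriched, centring on non-targeting sgRNAs 63 and 1, and edgeR on the recovered reads 51 and 26. Keeping sgRNAs of at least 100 in every baseline library, chosen after seeing the data, gave 10 and 1.

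RWPE-1 serves as the non-cancerous comparison. CREBBP and EP300, the paralogous acetyltransferases CBP and p300, were its most enriched genes, at 2.69 ± 0.24 (adjusted p = 1.53e-05) and 1.55 ± 0.17 (adjusted p = 3.98e-05), with all 10 sgRNAs of each higher. MLLT1, a reader of histone acylation, rose by 1.24 ± 0.13, L3MBTL2 by 1.18 ± 0.17, the transcription factor SP1 by 1.17 ± 0.15, and CHD1, a chromatin remodeller, by 1.09 ± 0.14. In the authors' deposited table CREBBP and EP300 were the RWPE-1 genes with an enrichment FDR under 0.05, at 0.0318 each. Relative to the non-targeting sgRNAs 6 genes were enriched and 430 depleted, with CREBBP at 2.06 and EP300 at 0.93, while CHD1 at 0.46 fell short of the size required. In total 166 genes were depleted and 66 enriched. The enriched count was 40 without RWPE-1 baseline replicate 2, 43 without baseline replicate 3 and 37 by edgeR.

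All 25 core essential controls fell in RWPE-1 (median -1.74, camera adjusted p = 7.27e-15; adjusted p = 0.307 with an estimated correlation), with PCNA at -2.26 ± 0.22, KPNB1 at -2.26 ± 0.15 and RPL7 at -2.24 ± 0.19. Outside that list SFPQ fell by 2.99 ± 0.20 (adjusted p = 2.41e-06), and SNRPF stood at -2.72 ± 0.16, TRMT112 at -2.45 ± 0.15, KANSL3 of the NSL acetyltransferase complex at -2.17 ± 0.17, PPP4C at -2.10 ± 0.25 and TOP2A at -2.07 ± 0.27. They were followed by RPS15A at -2.07 ± 0.18, FBL at -1.97 ± 0.20, SUPT16H at -1.91 ± 0.27 and the isoleucyl-tRNA synthetase gene IARS at -1.90 ± 0.16. For several lists the called members with the largest change were in this line. KMT2A at -1.68 ± 0.25 and HCFC1 at -1.54 ± 0.15 led COMPASS/MLL, TRRAP at -1.55 ± 0.15 and RUVBL1 at -1.37 ± 0.23 the NuA4, SRCAP and INO80 list, and SIN3A at -1.64 ± 0.21 and SAP130 at -1.57 ± 0.13 the SIN3 and NCOR list. RBBP4 at -1.24 ± 0.24 and CHD4 at -0.89 ± 0.15 led NuRD, and TADA2A at -1.17 ± 0.19 the SAGA/ATAC list.

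Single enzymes followed in RWPE-1. PRMT5 fell by 1.85 ± 0.36, with PRMT1 at -1.16 ± 0.17. The H3K9 corepressor TRIM28 fell by 1.64 ± 0.13, the demethylase KDM4A stood at -1.44 ± 0.17 and JMJD6 at -1.27 ± 0.20. The cell cycle kinases CDK1 and CHEK1 stood at -1.71 ± 0.17 and -1.70 ± 0.20, the histone chaperone NPM1 at -1.40 ± 0.27 and the remodeller CHD2 at -1.07 ± 0.17. WHSC1L1 rose by 0.85 ± 0.17, and stood at 0.22 relative to the non-targeting sgRNAs without passing (adjusted p = 0.266). RNF2 of PRC1, at 0.65 ± 0.16 (range 0.55 to 0.80), and HDAC10, at 0.56 ± 0.13 (range 0.50 to 0.62), lost their calls without RWPE-1 baseline replicate 3, and relative to the non-targeting sgRNAs they stood at 0.023 and -0.063. Among the tissue-restricted negative controls PRDM12 fell by 0.73 ± 0.15. PRDM14 stood at 0.53 ± 0.15, and at -0.10 relative to the non-targeting sgRNAs, and lost its call without RWPE-1 baseline replicate 1 or 3 or RWPE-1 endpoint replicate 2 (range 0.43 to 0.69). Of the genes named for RWPE-1 edgeR did not call PRMT5 (-0.30, adjusted p = 0.271), TRRAP (-0.45, adjusted p = 0.0491), HDAC10 (0.48, adjusted p = 0.00117) or PRDM14 (0.41, adjusted p = 0.00722).

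**Figure D1:**
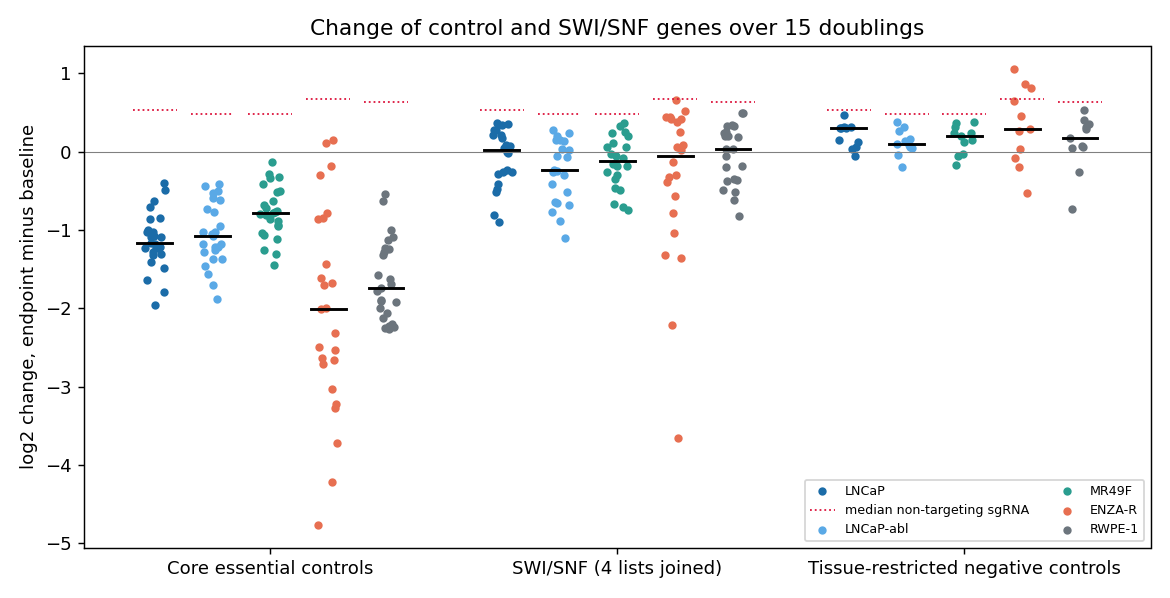
Log2 change from baseline to endpoint (y axis) of each gene in 3 lists, by line (colour); black bars are list medians and dotted red bars the mean over endpoint libraries of the median non-targeting sgRNA. Core essential controls lie lowest, with medians from -2.01 in ENZA-R to -0.78 in MR49F, and SWI/SNF medians lie between -0.24 and 0.030, all under the dotted bars.

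The SWI/SNF remodelling complexes are named in the purpose of the series. Joined, their 22 measured members did not shift as a group by the camera test in any line. The median was 0.016 in LNCaP, -0.24 in LNCaP-abl, -0.12 in MR49F, -0.056 in ENZA-R and 0.030 in RWPE-1, with camera adjusted p of 0.916, 0.288, 0.641, 0.535 and 0.868. In LNCaP the median lay above 0 while the test pointed down, and centring on non-targeting sgRNAs placed the LNCaP and RWPE-1 medians at -0.49 and -0.60. Without single libraries the median turned sign in LNCaP, ENZA-R and RWPE-1: -0.0040, -0.040 and -0.064 without LNCaP baseline replicate 2, baseline replicate 3 and endpoint replicate 1, 0.018 and 0.11 without ENZA-R endpoint replicates 2 and 3, and -0.00059 and -0.078 without RWPE-1 endpoint replicates 1 and 2. Single members did fall. ARID1A, the largest subunit of the canonical BAF form, fell by 0.90 ± 0.14 in LNCaP, stood at -0.64 ± 0.11 in LNCaP-abl and -0.70 ± 0.12 in MR49F, both called, and changed by 0.20 ± 0.15 in RWPE-1, a line named here after the value was seen. ARID2 of the PBAF form fell by 0.81 ± 0.13 in LNCaP and stood at -1.11 ± 0.10 in LNCaP-abl and -0.51 ± 0.16 in RWPE-1, the last a call lost without RWPE-1 baseline replicate 1 or 3 or RWPE-1 endpoint replicate 2 (range -0.65 to -0.34).

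LNCaP-abl had 7 of the 22 members depleted: besides ARID2 and ARID1A these were SMARCD2 at -0.89 ± 0.12, SMARCB1 at -0.77 ± 0.11, ACTL6A at -0.68 ± 0.20, SMARCC1 at -0.66 ± 0.13 and SMARCD1 at -0.52 ± 0.12. LNCaP had 3, with SMARCD1 at -0.52 ± 0.11. MR49F had 3, with SMARCC2 at -0.74 ± 0.12 and SMARCB1 at -0.67 ± 0.12. RWPE-1 had 3, with ACTL6A at -0.83 ± 0.17 and SMARCD2 at -0.61 ± 0.18. Adjusted over the list alone the counts were 3, 7, 3, 0 and 3 from LNCaP through LNCaP-abl, MR49F and ENZA-R to RWPE-1. Over all 779 genes 160, 140, 145, 6 and 166 were depleted in that order. Thus 3 of 22 was not a larger share than over all genes, while 7 of 22 in LNCaP-abl was. SMARCD1 lost its call in LNCaP without LNCaP baseline replicate 3 (range -0.65 to -0.22) and in LNCaP-abl without LNCaP-abl baseline replicate 1 or 3 or LNCaP-abl endpoint replicate 2 (range -0.63 to -0.42). In LNCaP-abl ACTL6A lost its call without LNCaP-abl baseline replicate 2 or 3 or LNCaP-abl endpoint replicate 1 (range -0.83 to -0.38) and SMARCC1 without LNCaP-abl baseline replicate 2 (range -0.75 to -0.45). SMARCB1 in MR49F was not called without MR49F baseline replicate 1 (range -0.76 to -0.49), nor SMARCD2 in RWPE-1 without RWPE-1 baseline replicate 2 or 3 or RWPE-1 endpoint replicate 3 (range -0.78 to -0.41). edgeR on the recovered reads called 2, 4, 3, 2 and 1 members in the same order, leaving out ARID2 (-0.25, adjusted p = 0.0628) and SMARCD1 (-0.46, adjusted p = 0.000919) in LNCaP, ARID2 (-0.37, adjusted p = 0.00628), ACTL6A (-0.25, adjusted p = 0.0938) and SMARCC1 (-0.34, adjusted p = 0.0192) in LNCaP-abl and ACTL6A (-0.45, adjusted p = 0.0336) and ARID2 (-0.35, adjusted p = 0.0404) in RWPE-1.

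In ENZA-R limma called 0 SWI/SNF members, with 2 at an unadjusted p under 0.05 and 2 called by edgeR. The lowest, named here after their values were seen, were SMARCC2 at -3.65 ± 0.89 (adjusted p = 0.111), ARID1B at -2.21 ± 1.14 (adjusted p = 0.349), ACTL6A at -1.36 ± 0.87 (adjusted p = 0.437) and ARID1A at -1.32 ± 0.36 (adjusted p = 0.143). In edgeR on the recovered reads SMARCC2 had an adjusted p of 0.00178 and ARID1A of 0.00110. The authors' deposited table for ENZA-R ranked SMARCC2 at 4 and ARID1A at 17 for depletion, with log2 fold changes of -3.55 and -1.93. By subunit list, in the line order used above, depleted members were 1, 5, 2, 0 and 2 of 11 for the core, 1, 1, 1, 0 and 0 of 6 for canonical BAF and 1, 1, 0, 0 and 1 of 4 for PBAF. BRD9, the single measured member of the non-canonical form, named after its values were seen, changed by 0.21, -0.066, 0.061, 0.062 and 0.027 and was not called in these lines.

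Depleted members of the other lists are counted from LNCaP through LNCaP-abl, MR49F and ENZA-R to RWPE-1. Adjusting over the list alone gave the same counts unless another is given. Histone chaperones had 7, 7, 7, 0 and 7 of 21, with 1 in LNCaP and 1 in RWPE-1 enriched, and chromatin kinases 7, 5, 3, 0 and 6 of 14 (7, 5, 3, 1 and 6 adjusted over the list alone), with 1 in LNCaP and 1 in RWPE-1 enriched. COMPASS/MLL had 8, 6, 8, 0 and 7 of 19 (8, 6, 8, 1 and 7 adjusted over the list alone), with 1 in LNCaP-abl, 1 in MR49F and 2 in RWPE-1 enriched (1 in LNCaP-abl, 1 in MR49F, 1 in ENZA-R and 2 in RWPE-1 adjusted over the list alone), and the NuA4, SRCAP and INO80 list 9, 7, 11, 0 and 11 of 31, with 1 in LNCaP-abl and 2 in RWPE-1 enriched. SAGA/ATAC had 5, 6, 1, 0 and 3 of 19 (5, 6, 1, 1 and 3 adjusted over the list alone), and SIN3 and NCOR 2, 3, 4, 0 and 4 of 18, with 2 in LNCaP, 1 in LNCaP-abl, 1 in MR49F and 1 in RWPE-1 enriched. The HBO1, MOZ, MSL and NSL acetyltransferases had 3, 4, 4, 1 and 4 of 18, with 2 in LNCaP and 1 in RWPE-1 enriched, and arginine methylation genes 2, 2, 2, 0 and 3 of 9, with 1 in RWPE-1 enriched. ISWI and CHD remodellers had 3, 2, 3, 0 and 1 of 18, with 3 in LNCaP, 1 in MR49F and 2 in RWPE-1 enriched (3 in LNCaP, 1 in MR49F, 1 in ENZA-R and 2 in RWPE-1 adjusted over the list alone), and NuRD 1, 1, 1, 0 and 2 of 14, with 1 in LNCaP-abl enriched. PRC2 had 2, 1, 1, 0 and 1 of 9 (2, 1, 1, 1 and 1 adjusted over the list alone), with 1 in RWPE-1 enriched, and PRC1 2, 0, 1, 0 and 0 of 21, with 2 in MR49F and 1 in RWPE-1 enriched. H3K9 methylation and HP1 genes had 1, 1, 1, 0 and 3 of 12, with 1 in LNCaP, 1 in MR49F, 1 in ENZA-R and 3 in RWPE-1 enriched (1 in LNCaP, 1 in MR49F, 2 in ENZA-R and 3 in RWPE-1 adjusted over the list alone), and Jumonji demethylases 2, 0, 2, 0 and 4 of 19, with 1 in RWPE-1 enriched. SET-domain methyltransferases had 1, 1, 1, 0 and 1 of 16, with 1 in LNCaP, 2 in MR49F and 2 in RWPE-1 enriched, and CoREST/LSD1 1, 0, 2, 0 and 0 of 9, with 2 in RWPE-1 enriched. DNA methylation genes had 1, 0, 1, 0 and 0 of 15, and HDAC and sirtuin enzymes 0, 1, 0, 0 and 0 of 12, with 1 in RWPE-1 enriched (1 in ENZA-R and 1 in RWPE-1 adjusted over the list alone). BET and p300/CBP genes had 3, 2, 1, 0 and 0 of 6, with 3 in RWPE-1 enriched, and their RWPE-1 median of 0.79 did not pass (camera adjusted p = 0.0736). Androgen signalling genes had 2, 1, 1, 0 and 0 of 7 (2, 1, 1, 2 and 0 adjusted over the list alone), with 1 in RWPE-1 enriched (0 adjusted over the list alone), tissue-restricted negative controls 0, 0, 0, 0 and 1 of 11, with 1 in RWPE-1 enriched, core essential controls 23, 23, 20, 2 and 25 of 25 (23, 23, 20, 17 and 25 adjusted over the list alone) and growth-restraining genes 0, 0, 0, 0 and 1 of 3, with 3 in LNCaP, 1 in LNCaP-abl, 1 in MR49F and 1 in RWPE-1 enriched (3 in LNCaP, 1 in LNCaP-abl, 1 in MR49F, 2 in ENZA-R and 1 in RWPE-1 adjusted over the list alone). By camera 4, 3, 3, 1 and 1 of 27 lists passed, all named with their line, and with an estimated correlation 0 passed in each line. The median and the test differed in sign for 5, 3, 3, 6 and 1 lists, of which 0 passed.

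Depletion was largely shared between lines. In LNCaP, LNCaP-abl, MR49F and RWPE-1, 231 genes were depleted in at least 1 line and 88 in all 4, of which 19 were core essential controls. LNCaP shared 121 depleted genes with LNCaP-abl, against 28.8 for independent lists, 118 with MR49F against 29.8 and 118 with RWPE-1 against 34.1. These pairs of lines share no libraries.

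**Figure D2:**
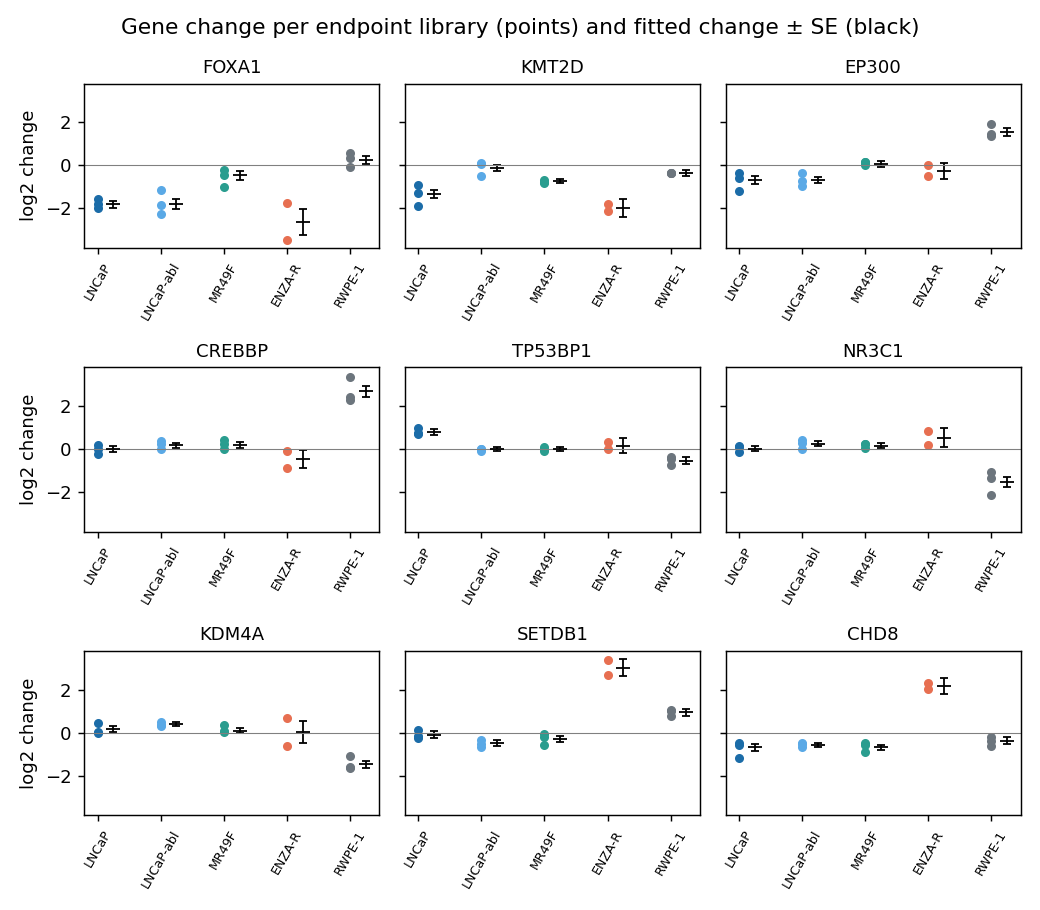
Log2 change of 9 genes (panels, y axis) in each line (x axis); coloured points are endpoint libraries relative to the line's baseline mean and black marks the fitted change ± SE. CREBBP and EP300 stand above 0 in RWPE-1, at 2.69 and 1.55, and SETDB1 and CHD8 stand above 0 in ENZA-R, where CHD8 was not called within the line.

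Comparisons between lines tested the difference of the changes. Each line but LNCaP-abl and RWPE-1 was processed in a batch of its own, and the 4 tables were normalised separately, so line and batch cannot be told apart except between LNCaP-abl and RWPE-1, which share both. MR49F minus LNCaP compares a line resistant to enzalutamide and grown with it with a line whose labels name no enzalutamide. Resistance, the drug in the medium, the history of the line and batch cannot be told apart in this comparison. FOXA1 differed by 1.34 ± 0.29 (adjusted p = 0.0208), with changes of -0.46 in MR49F and -1.81 in LNCaP. SS18L2 differed by 1.09 ± 0.21, SETD1B, a COMPASS methyltransferase, by 0.98 ± 0.18 with 0.54 in MR49F and -0.44 in LNCaP, and ZNF217 by 0.96 ± 0.17. TP53BP1, enriched in LNCaP, differed by -0.80 ± 0.17. In all 13 genes differed, 2 lower and 11 higher. The growth-restraining list lay lower in MR49F, with 2 of 3 called (median -0.80, camera adjusted p = 0.0103; adjusted p = 0.269 with an estimated correlation). Core essential controls lay higher, with 3 of 25 called (median 0.37, camera adjusted p = 2.67e-06, and adjusted p = 0.269 with an estimated correlation). Depletion of these controls was thus weaker in MR49F than in LNCaP, and whether the 11 higher genes differ beyond that was not tested.

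The calls for these differences were lost without some single libraries, while the differences kept their direction. FOXA1 was not called without LNCaP baseline replicate 2, MR49F baseline replicate 1 or 3 or MR49F endpoint replicate 1 or 2 (range 1.10 to 1.57), nor TP53BP1 without LNCaP baseline replicate 3, MR49F baseline replicate 2 or 3 or MR49F endpoint replicate 2 (range -0.86 to -0.68). SS18L2 was not called without LNCaP baseline replicate 1 or MR49F baseline replicate 3 (range 0.86 to 1.24), SETD1B without MR49F baseline replicate 3 (range 0.87 to 1.20) and ZNF217 without MR49F baseline replicate 1 (range 0.71 to 1.12). The count of 13 was 8 without LNCaP baseline replicate 2, 8 without baseline replicate 3 and 24 without endpoint replicate 3. It was 7, 8 and 3 without MR49F baseline replicates 1, 2 and 3, and 6 without MR49F endpoint replicate 2. The mean over sgRNAs gave 25 and edgeR 21. Of SWI/SNF members limma called 0, with 3 at an unadjusted p under 0.05 and 0 called by edgeR (list median -0.088, camera adjusted p = 0.669). edgeR did not call SS18L2 (0.13, adjusted p = 0.822), and relative to the non-targeting sgRNAs TP53BP1 stood at -0.77 without passing (adjusted p = 0.0521).

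ENZA-R minus LNCaP gave 25 genes, 8 lower and 17 higher in ENZA-R. SETDB1 stood highest, at 3.12 ± 0.35 (adjusted p = 0.00220), then CHD8, a remodeller, at 2.84 ± 0.34, TAF5L of SAGA at 2.40 ± 0.48 and the methyltransferase KMT2B at 2.01 ± 0.29. The lowest were PHIP at -2.95 ± 0.62, RPL18 at -2.84 ± 0.37, HMGB1 at -2.77 ± 0.53, USP7 at -2.71 ± 0.44, KAT8 at -2.67 ± 0.33 and SFMBT1 at -1.26 ± 0.24. Core essential controls lay lower (median -0.98, camera adjusted p = 0.000320; adjusted p = 0.0755 with an estimated correlation), with 2 of 25 called lower and 1 higher. Of SWI/SNF members limma called 0, with 2 at an unadjusted p under 0.05 and 2 called by edgeR (list median -0.096, camera adjusted p = 0.406). SMARCC2, named after its value was seen, differed by -3.64 ± 0.89 without passing (adjusted p = 0.0613).

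SETDB1, CHD8, KMT2B, RPL18 and KAT8 kept their ENZA-R minus LNCaP calls in all 10 fits that left out 1 library. USP7 was not called without LNCaP baseline replicate 3 or ENZA-R baseline replicate 2 or 3 (range -3.36 to -2.07). HMGB1 was called only without ENZA-R baseline replicate 2 or 3 or ENZA-R endpoint replicate 2 or 3 (range -3.81 to -2.08), TAF5L only without ENZA-R endpoint replicate 2 or 3 or LNCaP endpoint replicate 2 (range 1.16 to 2.70), SFMBT1 only without ENZA-R endpoint replicate 2 or 3 or LNCaP endpoint replicate 1 (range -1.38 to -1.12) and PHIP only without ENZA-R endpoint replicate 2 or 3 (range -3.90 to -2.01). The count was 8, 11 and 7 without LNCaP baseline replicates 1, 2 and 3, and 14, 11 and 8 without LNCaP endpoint replicates 1, 2 and 3. It was 12 without ENZA-R baseline replicate 2, 163 without ENZA-R endpoint replicate 2 and 247 without ENZA-R endpoint replicate 3. The counts without an ENZA-R endpoint library are likely too high, since the group with the widest spread then adds nothing to the error. In data simulated at the median spread of these libraries 24 of 140 calls fell on unchanged genes. The balance of directions also turned: the mean over sgRNAs gave 47 calls, 37 lower and 10 higher, of which 12 were shared with the 25, sgRNAs of at least 100 at baseline, chosen after seeing the data, gave 14 lower and 11 higher, and the fit without ENZA-R baseline replicate 3 gave 9 and 8. Centred on non-targeting sgRNAs, which moved the median difference from 0.097 to -0.068, the split was 9 lower and 9 higher. TAF5L then stood at 2.23 without passing (adjusted p = 0.0543), and edgeR did not call RPL18 (-0.55, adjusted p = 0.229), USP7 (-0.76, adjusted p = 0.111) or KAT8 (0.22, adjusted p = 0.683).

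LNCaP-abl minus LNCaP gave 17 genes, 5 lower and 12 higher. KMT2D differed by 1.22 ± 0.27 (adjusted p = 0.0303), SS18L2 by 1.17 ± 0.28 and ELP3, the catalytic subunit of Elongator, by 1.08 ± 0.19, all depleted in LNCaP. Lower in LNCaP-abl, among others, were EXOSC3 of the RNA exosome at -0.88 ± 0.19, TP53BP1 at -0.81 ± 0.16, SIRT6 at -0.68 ± 0.15 and CHD7 at -0.65 ± 0.16. Of SWI/SNF members limma called 0, with 3 at an unadjusted p under 0.05 and 0 called by edgeR (list median -0.18, camera adjusted p = 0.0856), and by camera 0 of 27 lists passed.

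These LNCaP-abl minus LNCaP calls were fragile. ELP3 was not called without LNCaP baseline replicate 2 or 3 or LNCaP-abl endpoint replicate 2 (range 0.92 to 1.15), TP53BP1 without LNCaP baseline replicate 2 or 3, LNCaP-abl baseline replicate 3 or LNCaP-abl endpoint replicate 2 or 3 (range -0.92 to -0.69) and KMT2D without LNCaP baseline replicate 2 or 3, LNCaP-abl baseline replicate 1 or 3 or LNCaP-abl endpoint replicate 2 or 3 (range 0.96 to 1.44). EXOSC3 was called only without LNCaP-abl endpoint replicate 1, LNCaP baseline replicate 1 or LNCaP endpoint replicate 1, 2 or 3 (range -1.03 to -0.70) and SIRT6 only without LNCaP-abl baseline replicate 1, LNCaP-abl endpoint replicate 1 or LNCaP endpoint replicate 1, 2 or 3 (range -0.79 to -0.63). SS18L2 was called only without LNCaP-abl endpoint replicate 1 or LNCaP endpoint replicate 1 or 3 (range 0.89 to 1.38) and CHD7 only without LNCaP-abl endpoint replicate 1 or LNCaP endpoint replicate 2 (range -0.74 to -0.53). The limma count was 10, 0 and 0 without LNCaP baseline replicates 1, 2 and 3, and 8 and 30 without LNCaP endpoint replicates 2 and 3. It was 3, 5 and 1 without LNCaP-abl baseline replicates 1, 2 and 3, and 0 and 1 without LNCaP-abl endpoint replicates 2 and 3. With all libraries 95 genes had an unadjusted p under 0.05, and edgeR called 5 lower and 11 higher. Centred on non-targeting sgRNAs it was 2 lower and 8 higher. SIRT6 then stood at -0.65 (adjusted p = 0.0640) and CHD7 at -0.62 (adjusted p = 0.168), without passing, and edgeR did not call EXOSC3 (-0.32, adjusted p = 0.276), SIRT6 (-0.32, adjusted p = 0.215) or SS18L2 (0.28, adjusted p = 0.477).

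LNCaP-abl minus RWPE-1, the comparison within a table, gave 99 genes, 46 lower and 53 higher. Among the lowest were CREBBP, which differed by -2.50 ± 0.29 (adjusted p = 3.73e-05), EP300 by -2.22 ± 0.23, FOXA1 by -2.04 ± 0.31, SETDB1 by -1.44 ± 0.22 and SP1 by -1.43 ± 0.18. EP300 was depleted in LNCaP-abl, at -0.67, and enriched in RWPE-1, at 1.55. The BET and p300/CBP list lay lower in LNCaP-abl, with 3 of 6 called (median -1.21, camera adjusted p = 0.00286; adjusted p = 0.139 with an estimated correlation). The highest were KDM4A by 1.86 ± 0.19, NR3C1, the glucocorticoid receptor, by 1.80 ± 0.30, SAP130 by 1.62 ± 0.16 and the histone chaperone SET by 1.39 ± 0.27, all of which fell in RWPE-1. Core essential controls lay higher in LNCaP-abl, with 7 of 25 called (median 0.54, camera adjusted p = 1.37e-05, and adjusted p = 0.168 with an estimated correlation). Depletion of these controls was thus weaker than in RWPE-1, and whether the 53 higher genes differ beyond that was not tested.

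SWI/SNF members lower in LNCaP-abl than in RWPE-1 were SMARCC1 at -0.99 ± 0.22, ARID1A at -0.84 ± 0.18, SMARCD1 at -0.71 ± 0.22 and SMARCC2 at -0.65 ± 0.19, with a list median of -0.12 (camera adjusted p = 0.0782). Within the lines SMARCC2 changed by -0.41 ± 0.14 in LNCaP-abl and 0.23 ± 0.12 in RWPE-1 and was called in neither. The difference for SMARCD1 was called only without LNCaP-abl baseline replicate 2, RWPE-1 baseline replicate 1 or RWPE-1 endpoint replicate 2 (range -0.90 to -0.55). SMARCC2 was not called without LNCaP-abl baseline replicate 2 or 3, LNCaP-abl endpoint replicate 3 or RWPE-1 baseline replicate 1 or 2 (range -0.75 to -0.48), nor SET without RWPE-1 baseline replicate 1 (range 1.15 to 1.70), while the other genes named for LNCaP-abl against RWPE-1 passed in all 12 such fits. The count of 99 was 65 without RWPE-1 baseline replicate 2. Centring on non-targeting sgRNAs moved the median difference from 0.0083 to 0.16 and the split to 28 lower and 72 higher, while edgeR gave 42 and 39. With that centring SMARCD1 stood at -0.56 (adjusted p = 0.0753) and SMARCC2 at -0.49 (adjusted p = 0.122), without passing. Of SWI/SNF members edgeR called 2, leaving out SMARCD1 (-0.43, adjusted p = 0.0951) and SMARCC2 (-0.45, adjusted p = 0.0602).

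LNCaP minus RWPE-1 gave 103 genes, 48 lower and 55 higher. CREBBP differed by -2.68 ± 0.30 (adjusted p = 4.31e-05), EP300 by -2.23 ± 0.26, FOXA1 by -2.05 ± 0.24 and ZNF217 by -1.74 ± 0.29. KDM4A by 1.62 ± 0.22, NR3C1 by 1.57 ± 0.29, SFPQ by 1.52 ± 0.30 and SMEK1 by 1.49 ± 0.20 were higher in LNCaP. SFPQ was depleted in both lines, at -1.47 in LNCaP and -2.99 in RWPE-1. The BET and p300/CBP list lay lower in LNCaP, with 4 of 6 called (median -1.59, camera adjusted p = 0.000415; adjusted p = 0.0623 with an estimated correlation). Androgen signalling genes lay lower too, with 2 of 7 called (median -0.40, camera adjusted p = 0.0391; adjusted p = 0.180 with an estimated correlation). The SIN3 and NCOR list lay higher, with 5 of 18 called higher and 1 lower (median 0.37, camera adjusted p = 0.0222; adjusted p = 0.180 with an estimated correlation). Core essential controls lay higher, with 8 called (median 0.43, camera adjusted p = 0.000415, and adjusted p = 0.180 with an estimated correlation). Depletion of these controls was thus weaker in LNCaP than in RWPE-1, and whether the 55 higher genes differ beyond that was not tested.

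SWI/SNF members lower in LNCaP than in RWPE-1 were ARID1A at -1.10 ± 0.20, SMARCA4, an ATPase of the complex, at -0.75 ± 0.20 and SMARCD1 at -0.71 ± 0.21, while the list median was 0.025 with the camera test pointing down (camera adjusted p = 0.749). Within the lines SMARCA4 changed by -0.26 ± 0.14 in LNCaP and 0.497 ± 0.14 in RWPE-1 and was called in neither. Its difference was not called without LNCaP endpoint replicate 1 or RWPE-1 baseline replicate 1 or 2 (range -0.90 to -0.67), and that of SMARCD1 was called only without LNCaP baseline replicate 1, RWPE-1 baseline replicate 1 or RWPE-1 endpoint replicate 2 (range -0.90 to -0.41). The count of 103 was 63 without RWPE-1 baseline replicate 1 and 68 without RWPE-1 baseline replicate 2. Centring on non-targeting sgRNAs moved the median difference from 0.027 to 0.15 and the split to 28 lower and 62 higher, while edgeR gave 60 and 30 and the mean over sgRNAs 64 and 61. With that centring SMARCA4 stood at -0.63 (adjusted p = 0.0665) and SMARCD1 at -0.59 (adjusted p = 0.0968), without passing. Of SWI/SNF members edgeR called 1, leaving out SMARCA4 (-0.44, adjusted p = 0.0949) and SMARCD1 (-0.38, adjusted p = 0.206), and of the other genes named it did not call SFPQ (0.56, adjusted p = 0.312).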

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

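The tests of the non-targeting rise against the authors' scaling, of the ENZA-R spread and of other splits of the samples, and the set of genes in the X-linked test, were chosen only after the results were seen; the test on shuffled sgRNAs was written before.

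Non-targeting sgRNAs, which the main fits left out, gave a signal of their own. Their median log2 change was 0.56 in LNCaP, 0.44 in LNCaP-abl, 0.49 in MR49F, 0.56 in ENZA-R and 0.56 in RWPE-1, with 79, 75, 75, 63 and 76 of 80 above 0. Scaling by the authors to a library in which most genes cost growth would lift negative control genes as much. Over the 4 lines other than ENZA-R, however, 8 sets of 10 non-targeting sgRNAs averaged 0.51 and 11 tissue-restricted genes 0.15, a gap of 0.366 (exact permutation test, two-sided, p = 2.65e-05), which argues against scaling as the whole cause. A cost of DNA cutting, which non-targeting guides escape, stays open: outside the core essential list 36 X-linked genes lay 0.190 above 712 autosomal genes (permutation test, p = 0.00931). Copy number was not analysed here, and no biological explanation was tested.

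The changes in ENZA-R spread more widely than in the other lines. Sequencing depth is argued against, since the lowest median of reads per sgRNA in an ENZA-R library was 632 and that of the other lines 374. Stronger selection as the whole cause is argued against too, because sgRNAs with no gene to select on had an SD 3.40 times the highest of the other lines. Drift from few cells per sgRNA stays open, with an SD of 1.42 over the non-targeting sgRNAs. A batch of its own and a biological difference of ENZA-R cells also stay open, as untested.

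ENZA-R and LNCaP differed in 25 genes. PHIP at -2.95, RPL18 at -2.84, HMGB1 at -2.77, USP7 at -2.71, KAT8 at -2.67 and SFMBT1 at -1.26 lay lower, and KMT2B at 2.01, TAF5L at 2.40, CHD8 at 2.84 and SETDB1 at 3.12 higher. Of 100 shuffles that dealt the sgRNAs out to genes at random, 0 gave as many as the 17 higher genes (highest 6). For the 8 lower genes 1 of 100 did (highest 9). This argues against drift of single sgRNAs as the cause of the whole count of 17. Drift as the cause of some of these genes stays open. The shuffles hold no changed genes, while in the simulation that held them 24 of 140 calls fell on unchanged genes. The mean over sgRNAs gave 10 higher genes. Batch, enzalutamide and the history of the line cannot be told apart here because the line was processed in a batch of its own. With 2 libraries per ENZA-R group, other splits of these samples were not counted.

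Tests of the difference between lines picked out the other comparisons. Between MR49F and LNCaP 13 genes differed, with TP53BP1 at -0.80 lower and ZNF217 at 0.96, SETD1B at 0.98, SS18L2 at 1.09 and FOXA1 at 1.34 higher. Between LNCaP-abl and LNCaP it was 17 genes, with EXOSC3 at -0.88, TP53BP1 at -0.81, SIRT6 at -0.68 and CHD7 at -0.65 lower and ELP3 at 1.08, SS18L2 at 1.17 and KMT2D at 1.22 higher. Between LNCaP-abl and RWPE-1 99 genes differed, with CREBBP at -2.50, EP300 at -2.22, FOXA1 at -2.04, SETDB1 at -1.44, SP1 at -1.43, SMARCC1 at -0.99, ARID1A at -0.84, SMARCD1 at -0.71 and SMARCC2 at -0.65 lower and SET at 1.39, SAP130 at 1.62, NR3C1 at 1.80 and KDM4A at 1.86 higher. Between LNCaP and RWPE-1 it was 103, with CREBBP at -2.68, EP300 at -2.23, FOXA1 at -2.05, ZNF217 at -1.74, ARID1A at -1.10, SMARCA4 at -0.75 and SMARCD1 at -0.71 lower and SMEK1 at 1.49, SFPQ at 1.52, NR3C1 at 1.57 and KDM4A at 1.62 higher.

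Line labels were redrawn among baseline and among endpoint libraries in 100 splits, the real one included, and the comparisons are given in the order above. A first way relabelled values centred within each line, where the 12 splits that left the endpoint libraries parted by line keep the difference, so it had no way to give a share under 0.05; its counts of splits as large were 11, 12, 12 and 12, with real counts of 13, 17, 99 and 103 and highest others of 41, 24, 123 and 131. A second way, added after those counts were seen, centred the values after relabelling and gave 5, 9, 4 and 7 of 100, with highest others of 18, 362, 102 and 372. Here too a split that left the endpoint libraries parted by line keeps the difference, in all 4 comparisons. Splits that mixed the lines at the endpoint put differences between lines into the error, which lowers their counts. A share under 0.05 was reached only for LNCaP-abl against RWPE-1, by a margin of 1 split and in a way chosen after the first counts were seen. Because the share depends largely on how many splits left the lines parted, it does not decide in any of the 4 comparisons. Of the splits as large 5, 7, 4 and 7 left the endpoint libraries parted by line, and the highest count with the lines mixed at the endpoint was 7, 64, 4 and 1. Counts of 362 and 372, several times the real ones, came from splits that left the endpoint libraries parted by line, and point to a structure of the samples by line whose cause was not tested. Within a line the 6 libraries make 10 splits, too few for a share under 0.05: 1 split, the real one, gave as many genes in each line, with real counts of 193 in LNCaP, 148 in LNCaP-abl, 163 in MR49F and 232 in RWPE-1 and a highest other of 0 in each.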

How the results depend on the processing

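Keeping ENZA-R sgRNAs of at least 100 in every baseline library was chosen only after the data were seen; the other settings were set before. Of the values recomputed under settings other than a library left out, 129 kept their direction and their side of the threshold or stayed within 1.5 times, 27 moved further, 5 no longer passed and 4 changed sign; with a library left out it was 123, 40, 0 and 7. In the order LNCaP, LNCaP-abl, MR49F, ENZA-R and RWPE-1, centring on non-targeting sgRNAs gave 345, 327, 326, 63 and 430 depleted genes, where the authors' scaling gave 160, 140, 145, 6 and 166. It gave 1, 0, 0, 1 and 6 enriched genes, where the authors' scaling gave 33, 8, 18, 1 and 66, since by construction it lowers every gene. With no minimum size 135, 104, 119 and 123 genes were enriched in LNCaP, LNCaP-abl, MR49F and RWPE-1, as smaller changes then count. edgeR called 13, 4, 5, 26 and 37 enriched, and 51 depleted in ENZA-R. In ENZA-R the mean over sgRNAs gave 52 depleted and 3 enriched, and sgRNAs of at least 100 gave 10 depleted. For MR49F minus LNCaP (13 genes) the mean over sgRNAs gave 25 and edgeR 21, for ENZA-R minus LNCaP (25) the mean over sgRNAs gave 47, and for LNCaP-abl minus LNCaP (17) centring on non-targeting sgRNAs gave 10. Except where a setting's construction is named, the cause was not tested.

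Core essential medians of -1.17, -1.08, -0.78, -2.01 and -1.74 did not pass camera with an estimated correlation (adjusted p = 0.0652, 0.105, 0.365, 0.360 and 0.307). The SWI/SNF median turned negative in LNCaP with the mean over sgRNAs (-0.057) and with non-targeting centring (-0.49), and in RWPE-1 likewise (-0.0030 and -0.60); it passed camera in neither. It also turned without LNCaP baseline replicate 2 (-0.0040) or 3 (-0.040) or LNCaP endpoint replicate 1 (-0.064), without ENZA-R endpoint replicate 2 (0.018) or 3 (0.11), and without RWPE-1 endpoint replicate 1 (-0.00059) or 2 (-0.078).

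Over the fits that left out 1 library, depleted genes ran from 146 to 167 in LNCaP, 123 to 146 in LNCaP-abl, 131 to 147 in MR49F, 0 to 128 in ENZA-R and 140 to 169 in RWPE-1, and enriched genes from 31 to 46, 8 to 18, 16 to 24, 0 to 94 and 40 to 84. Genes that differ ran from 3 to 24 for MR49F minus LNCaP, 7 to 247 for ENZA-R minus LNCaP, 0 to 30 for LNCaP-abl minus LNCaP, 65 to 125 for LNCaP-abl minus RWPE-1 and 63 to 126 for LNCaP minus RWPE-1. The high ends for ENZA-R come from fits with a lone endpoint library and are likely too high. The SWI/SNF median ran from -0.064 to 0.090 in LNCaP, -0.23 to -0.13 in LNCaP-abl, -0.17 to -0.052 in MR49F, -0.13 to 0.11 in ENZA-R and -0.078 to 0.16 in RWPE-1. The core essential median ran from -1.19 to -1.02, -1.12 to -0.99, -0.87 to -0.60, -2.10 to -1.40 and -1.89 to -1.55 in the same order.

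With the replicate block the counts of depleted and enriched genes were 161 and 33 in LNCaP, 141 and 8 in LNCaP-abl, 145 and 18 in MR49F and 164 and 62 in RWPE-1. The block gave 10 genes for MR49F minus LNCaP, 11 for LNCaP-abl minus LNCaP, 84 for LNCaP-abl minus RWPE-1 and 91 for LNCaP minus RWPE-1. Same-numbered libraries correlated at 0.00572731 to 0.0705 in their deviations. Each correlated best with its own number in LNCaP, MR49F and RWPE-1, and in LNCaP-abl replicate 1 did. This points to a weak link between same-numbered libraries, which the main fits leave out and the fits with the replicate block take in. No paired analysis was made for ENZA-R because its columns carry the numbers 2 and 3 where the labels give 1 and 2. In ENZA-R 344 to 571 sgRNAs lay under 30 at baseline and 1190 to 1508 at the endpoint, at totals of 7468581 reads or more.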

Other observations

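The test of a null centred on the non-targeting sgRNAs was chosen only after the deposited FDR values were seen, and so was the choice of the 8 genes common to the cancer lines; the test on MPHOSPH8 was written before its value was looked at.

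In LNCaP, LNCaP-abl and MR49F together 96 genes were depleted, and 8 of these were not called in RWPE-1, among them ARID1A, BAP1, CHD8, DR1, MRGBP, OGT and RMI1, chosen after their values were seen. They were picked on these same libraries, so the differences below describe them and do not test the pattern. MRGBP of NuA4 differed by -1.15 ± 0.22 in LNCaP and -0.90 ± 0.23 in LNCaP-abl, ARID1A of BAF by -1.10 ± 0.20 and -0.84 ± 0.18, BAP1, a deubiquitinase of histone H2A, by -1.01 ± 0.22 and -0.93 ± 0.23, and DR1 of ATAC by -1.002 ± 0.24 and -0.93 ± 0.23. In LNCaP-abl minus RWPE-1 BAP1 was not called without LNCaP-abl baseline replicate 3 or RWPE-1 baseline replicate 2 or 3 (range -1.12 to -0.75), DR1 without LNCaP-abl baseline replicate 1 or 2 (range -1.14 to -0.78) and MRGBP without LNCaP-abl baseline replicate 1 (range -1.10 to -0.76). There MRGBP stood at -0.75 relative to the non-targeting sgRNAs without passing (adjusted p = 0.0576), and edgeR did not call DR1 (-0.35, adjusted p = 0.162). CHD8 differed by -0.30 ± 0.24 (adjusted p = 0.515) and -0.19 ± 0.19 (adjusted p = 0.579), OGT by -0.30 ± 0.26 and -0.41 ± 0.21, and RMI1 by -0.40 ± 0.23 and -0.40 ± 0.20, which did not pass. MR49F was not tested against RWPE-1.

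SETDB1 and its cofactor ATF7IP, the latter chosen after its value was seen, both lay higher in ENZA-R than in LNCaP, by 3.12 ± 0.35 (adjusted p = 0.00220) and 1.51 ± 0.28 (adjusted p = 0.0204). Within ENZA-R ATF7IP changed by 1.90 ± 0.35 without passing (adjusted p = 0.0729). The hypothesis tested was that loss of these genes may relieve silencing of an integrated transgene, in which case MPHOSPH8, a member of the HUSH silencing complex, would be higher too. MPHOSPH8 differed by 1.299 ± 0.31 (adjusted p = 0.0549), in the predicted direction, but it did not pass, so the test does not decide. In RWPE-1 SETDB1, ATF7IP and MPHOSPH8 were called enriched at 0.97 ± 0.15, 0.84 ± 0.13 and 0.67 ± 0.17, values looked at after the fact, but relative to the non-targeting sgRNAs they stood at 0.34, 0.22 and 0.047 without passing (adjusted p = 0.0637, 0.175 and 0.812).

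In the authors' deposited tables the depletion FDR was under 0.05 for 680, 687, 534, 455 and 668 of 779 genes in LNCaP, LNCaP-abl, MR49F, ENZA-R and RWPE-1. The enrichment FDR in the authors' deposited tables was under 0.05 for 1, 0, 0, 0 and 2. A candidate explanation is a null centred on the non-targeting sgRNAs, which lay above most genes. It needs most of the genes whose log2 fold change in the authors' deposited table lay between 0 and the non-targeting median to pass the depletion FDR. In the same order 77.9%, 81.1%, 46.1%, 46.9% and 77.7% passed, fewer than did not in MR49F and ENZA-R, so the explanation stays open, and MAGeCK's options are not given in the sources used here. The log2 changes computed here correlated across genes with those of the authors' deposited tables at 0.975, 0.976, 0.975, 0.894 and 0.978 in the same order, where genes are not independent replicates.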
